A study of Mus musculus with 6 samples.

How the data were processed

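Messenger RNA of whole spinal cord was measured in 6 untreated male C57Bl/6 mice aged 4 months, 3 wild type and 3 lacking Nogo-A, with 1 Affymetrix Mouse 430 2.0 array per animal. Each array holds short oligonucleotide probes grouped into probe sets, and each probe set reports on a transcript or a part of it. Per the labels, RNA of all animals was extracted on a single day, treated with DNase on the column and labelled with biotin after 1 round of in vitro transcription. The deposited values were intensities on a linear scale, which the authors obtained from the scanned arrays with MAS 5.0 in GCOS 1.4, per the submitters' processing notes and the series' design text. The mean of each array after removal of the lowest and highest 2% of values lay between 499.86 and 499.88, so the deposited intensities had already been scaled to a common target. All 45101 probe sets were listed, and no gene was centred, so the authors' later steps in GeneSpring 7.2 (a filter on present calls, division by chip and gene medians, and thresholds on p and fold) were not part of these values. Present calls were not used here.

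Each intensity was divided by the median of its array and converted to log2, after the per-chip median step named in the series' design text. The 64 control probe sets were left out. A probe set was tested where its value was at or above the 50th percentile of its array on at least 2 of 3 arrays of at least 1 genotype, which stood in for the filter on present calls and left 23525 probe sets. Knockout was compared with wild type in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The 1-factor test that the series' design text names was run as the methods' t-test on the same log2 values at an unadjusted p under 0.05 with a fold of at least 1.2 either way, and again after Benjamini-Hochberg adjustment. Labels gave the genotype of every array, and no scan date or batch was given in the sources used here. With 3 animals against 3, the number of arrays limits the precision, and an exact permutation test of a single value cannot give a p below 0.1.

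Gene names came from the platform annotation, updated through gene identifiers to a RefSeq gene table of assembly GRCm38.p6, in which 34754 of 35890 annotated probe sets were found. In that annotation 34945 probe sets had 1 symbol, 932 had several, and 9160 that were not controls were not listed and stay unnamed here. Of the tested probe sets, 20444 had 1 symbol and stood for 11645 genes, and 3081 did not have exactly 1. The deposited values name no genome build, so no coordinates are given, and the table served only for names and for which genes neighbour each other.

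The genotype comparison, its thresholds, 32 gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The rule named every Rtn4 probe set and, in each direction, the 12 genes with the smallest limma p among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the 3 knockout and 3 wild type values. Where fewer than 12 passed, the places were filled with the smallest p among probe sets with a fold of at least 1.2 and no overlap, which are reported as not past the threshold. Symbols of clones and predicted genes were skipped. The rule also took up to 4 members of each list with the smallest p, every member past the threshold adjusted over the list alone, and up to 5 genes near Rtn4. A gene in a list was represented by its tested probe set with the highest mean. Of the lists, 1 held sex markers as a check of the labels, and 1, of dorsal root ganglion genes, had too few tested members. The other 30 were tested with camera in limma at its preset correlation of 0.01, again with an estimated correlation, and with fry, and 1 of them is not reported here. List members were matched by current symbol.

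The model was tested on data simulated for the knockout and wild type comparison over 23525 probe sets, with 200 probe sets changed in each of 5 simulations. It recovered 0.287% of changes of 1.5-fold, 19.3% of changes of 2-fold and 74.3% of changes of 4-fold, and 10 of 312 calls were false. A list raised by 0.3 on the log2 scale was found in 5 of 5 simulations, with 1 other list called. The simulated noise was independent between probe sets. In the real data the estimated correlation was 0.434 in the myelin list and 0.775 in the oxidative phosphorylation list. The simulations therefore do not give the error rate of the list test on these arrays. Other settings tried were quantile normalization, the deposited scaling alone, no filter and filters at the 25th and 75th percentile, an offset of 0.25 of the array's median, eBayes without the trend, a replicate block, each array left out in turn, the mean of all probe sets of a gene, and windows of 5 and 20 Mb around Rtn4. Centring on the tested probe sets, and the deposited scaling without wild type replicate 3, were added after the data were seen.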

Results

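The series asked how the adult, uninjured spinal cord of mice lacking Nogo-A differs in gene expression from that of wild type mice. Nogo-A is a membrane protein of oligodendrocytes and some neurons that restrains axon growth, and it is the longest of the proteins made from the gene Rtn4. Spinal cords of 3 wild type and 3 Nogo-A knockout mice, all male and aged 4 months, were measured on 1 array each. Eif2s3y, a gene of the Y chromosome, had signals of 507 to 775 at its brightest probe set on all 6 arrays, and Xist, which silences an X chromosome in females, had at most 128 on any array and probe set.

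The arrays were not alike in their dim signals. The median signal was 148.2, 169.6 and 195.6 on wild type replicates 1 to 3 and 144.4, 149.3 and 144.1 on knockout replicates 1 to 3. The 5th percentile was 5.26, 10.5 and 19.98 on the wild type arrays and 4.57, 4.92 and 4.72 on the knockout arrays. Hybridization control transcripts on wild type replicate 3 were 0.725-fold those of the other 5 arrays, and its mean correlation with them over tested probe sets was 0.930, against 0.952 to 0.961 for the others. Genes of skeletal muscle also set arrays apart. Acta1, the actin of skeletal muscle, had a signal of 2142 on wild type replicate 3 and 4593 on knockout replicate 2, against 385 to 754 on the other 4 arrays, and the fast myosin gene Myh4 had 815 and 2151 there against 117 to 262.

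The targeted gene was measured by 5 probe sets, and they moved apart. The third brightest in wild type, called the lost probe set here, fell from 3051 ± 441 in wild type to 30.8 ± 41.1 in knockout (SD, n = 3 each), with knockout signals of 78.2, 9.17 and 5.08. It was lower in 3 of 3 knockout arrays (limma, Benjamini-Hochberg adjusted p = 0.000109). The fitted log2 change was -7.40 with a standard error of 0.66, and -5.45 with an offset of 0.25 of the array's median, so its size depends on dim knockout signals and is not given as a measured fold. All 3 knockout signals lay under the median of their array, and against that median the wild type signal was at least 17.8-fold higher. The other 4 probe sets of Rtn4, a gene that also encodes Nogo-B and Nogo-C, were brighter in knockout than in every wild type array. The second brightest read 8971 ± 945 in wild type and 13157 ± 863 in knockout, the fourth brightest read 1899 ± 405 and 2572 ± 71.7, the dimmest read 858 ± 138 and 1390.1 ± 215, and the brightest read 18854 ± 2989.5 and 24626 ± 94.0 (SD, n = 3 each). These 4 had an adjusted p of 0.382 each over all tested probe sets in limma, and adjusted over the list alone, that of the 5 Rtn4 probe sets, they had adjusted p-values of 0.00178 to 0.0117. That set was not among the fixed lists, and it includes the lost probe set, whose small p can ease the adjustment of the other 4. With the deposited scaling the 4 had adjusted p-values of 0.538 to 0.591 over all tested probe sets in limma, and the adjustment over the set alone was not repeated. The sources used here do not say which part of the gene a probe set covers, so the probe sets other than the lost one do not check the labels. Without the trend in eBayes the adjusted p of the lost probe set was 0.0610, and over all alternatives it ranged from 2.11e-124 to 0.0610. The smallest came from the replicate block, which treats the label's numbers as pairs although no pairing of the animals is known.

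**Figure D1:**
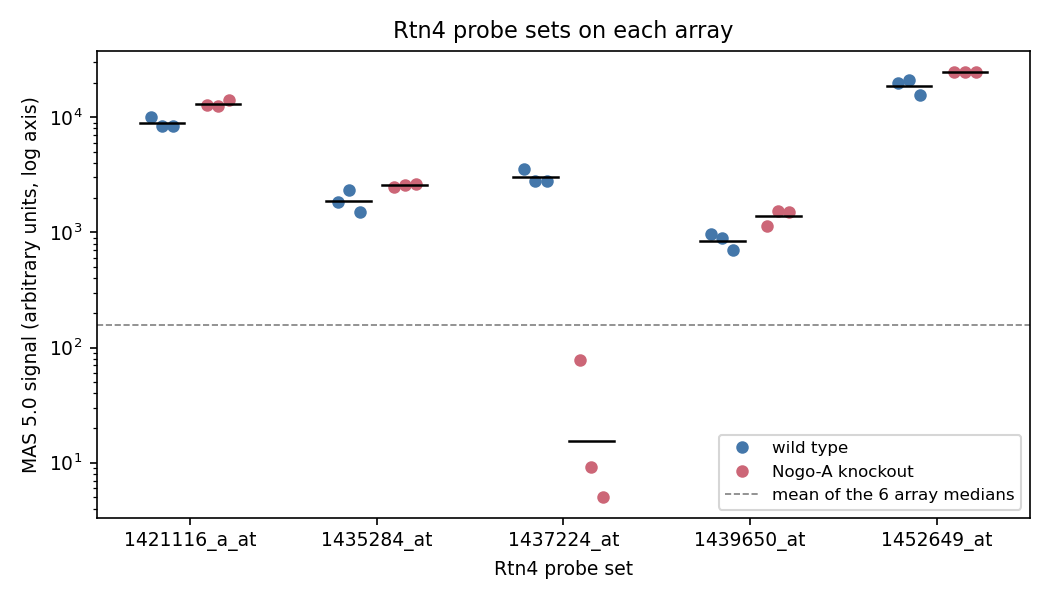
MAS 5.0 signal (arbitrary units, log axis) of the 5 Rtn4 probe sets on each array, with 3 wild type and 3 Nogo-A knockout arrays as points, a black line at the mean of the log2 signals of each genotype, and a dashed line at the mean of the 6 array medians. The knockout points of the lost probe set lie at 5.08 to 78.2 while the wild type points lie at 2790.4 to 3560.2, and the other 4 probe sets are brighter in knockout.

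Rtn4 alone passed the adjusted threshold in limma, a test that recovered 0.287% of 1.5-fold and 19.3% of 2-fold changes in the simulations. The lack of other calls therefore does not show that other genes were unchanged. Of 23525 probe sets tested, 1 was lower in knockout, the lost probe set of Rtn4, and 0 were higher at an adjusted p under 0.05 (limma). At an unadjusted p under 0.05, 2805 were higher and 265 lower, and the median log2 change of all tested probe sets was 0.23. With the deposited scaling these counts were 1013 higher and 937 lower, with a median change of 0.0079, and after quantile normalization they were 863 and 658, with a median of 0.019. Because the scaling moved the median by this much, log2 changes and folds of genes and lists below are given relative to the shift of 0.23, while the p-values come from the unshifted fit. The methods' t-test gave 1964 probe sets higher and 217 lower at the thresholds of the series design, 0 after Benjamini-Hochberg adjustment (smallest adjusted p = 0.225), and with the deposited scaling 527 higher and 609 lower. Leaving out wild type replicate 1, 2 or 3 gave 640, 1 and 7 probe sets higher and 38, 2 and 3 lower, and leaving out knockout replicate 1 gave 2 higher and 1 lower. The methods' t-test called 5423, 1073 and 1382 probe sets without wild type replicates 1, 2 and 3, and 963 and 931 without knockout replicates 1 and 3.

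None of the 12 genes that led the higher side passed the threshold. Lbh, a cofactor of transcription, read 391 ± 115 in wild type and 782 ± 127 in knockout (SD, n = 3 each), 2.03-fold relative to the shift (limma adjusted p = 0.105). Pltp, which moves phospholipids between lipoproteins, was 1.75-fold, Apoc1, an apolipoprotein, was 3.32-fold with mean signals of 104 and 324, and Agpat3, an acyltransferase of phospholipid synthesis, was 1.80-fold. The ubiquitin ligase Rnf167 was 1.79-fold (1263 ± 171 to 2262 ± 140, adjusted p = 0.227 in limma) and Ube2v1, a partner of a conjugating enzyme, was 1.64-fold. The collagen genes Col6a2 and Col1a1 were 2.62-fold and 1.96-fold, and the laminin receptor subunit Itga3 was 1.52-fold. Unc50, a Golgi protein, read 1403 ± 428 and 3029.7 ± 109, or 2.22-fold (adjusted p = 0.217 in limma). The clathrin adaptor subunit Ap2a1 was 1.57-fold. Txnrd2, the mitochondrial thioredoxin reductase, read 73.6 ± 25.4 and 273 ± 68.9, and because its wild type signals all lay under the array median its fold is given as at least 1.83. This bound is taken against the array median and not relative to the shift. By the rule that named them, each of the 12 was higher in 3 of 3 knockout arrays than in every wild type array. Over all tested probe sets, 21.9% had no overlap between the genotypes in either direction, where 10% is the share by chance. The share of 21.9% comes from the median-scaled values, which carry the shift, and it was not computed under another scaling.

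The 11 genes that followed Rtn4 on the lower side did not pass either, and most were dim. Spred2, an inhibitor of Ras and ERK signalling, read 638 ± 257 in wild type and 188 ± 21.6 in knockout, a fold of 0.306 relative to the shift (SD, n = 3 each, limma adjusted p = 0.153). Ddx5, an RNA helicase, had a fold of 0.312 at the probe set with its smallest p, Ezr, which ties actin to the cell membrane, 0.395, the F-box gene Fbxo36 0.438, and Ndufs8, a subunit of respiratory complex I, 0.382. Knockout signals of Utf1, Samhd1, Ppp1r13l, Sec14l3, Igbp1 and Klf3 all lay under the array median, and wild type was at least 1.57-fold, 1.51-fold, 1.92-fold, 1.46-fold, 1.70-fold and 1.57-fold higher in that order. These bounds are against the array median and not relative to the shift. Signals rose from wild type replicate 1 to 3, as the dim signals of those arrays did, in Utf1, Ddx5, Ezr, Fbxo36, Ppp1r13l, Sec14l3 and Igbp1. They were 417, 1080.5 and 1851 in Ddx5 and 148, 395 and 598 in Ppp1r13l, against highest knockout signals of 379 and 143. Spred2, Samhd1, Klf3 and Ndufs8 did not rise in that order. At an unadjusted p under 0.05 in limma, other probe sets of the lower-side genes were also lower in Ddx5 and Klf3 only, 1 each, with a relative log2 change of -1.75 in Ddx5 and -0.92 in Klf3. Without that threshold, the 3 other probe sets of Samhd1 all lay under the shift, at -0.47 to -0.034, and the brightest other probe set had the same direction in 2 of 8 genes. Of 8 genes with another tested probe set, Rtn4 left out, the brightest other probe set changed by less than 0.25 of the named change in 8, and the named probe set was the dimmer in 7. The brightest other probe set of Ddx5 had a relative log2 change of 0.026, that of Ndufs8 0.17 and that of Spred2 0.058. On the higher side the brightest other probe set changed by less than 0.25 of the named change in 5 of 8 genes, and it had the same direction in 6. Pltp had 0.42 at its brighter probe set. The other probe sets of Unc50 had relative log2 changes of -0.021 and -0.57, and that of Ube2v1 had -0.00014, so they did not follow the named ones.

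**Figure D2:**
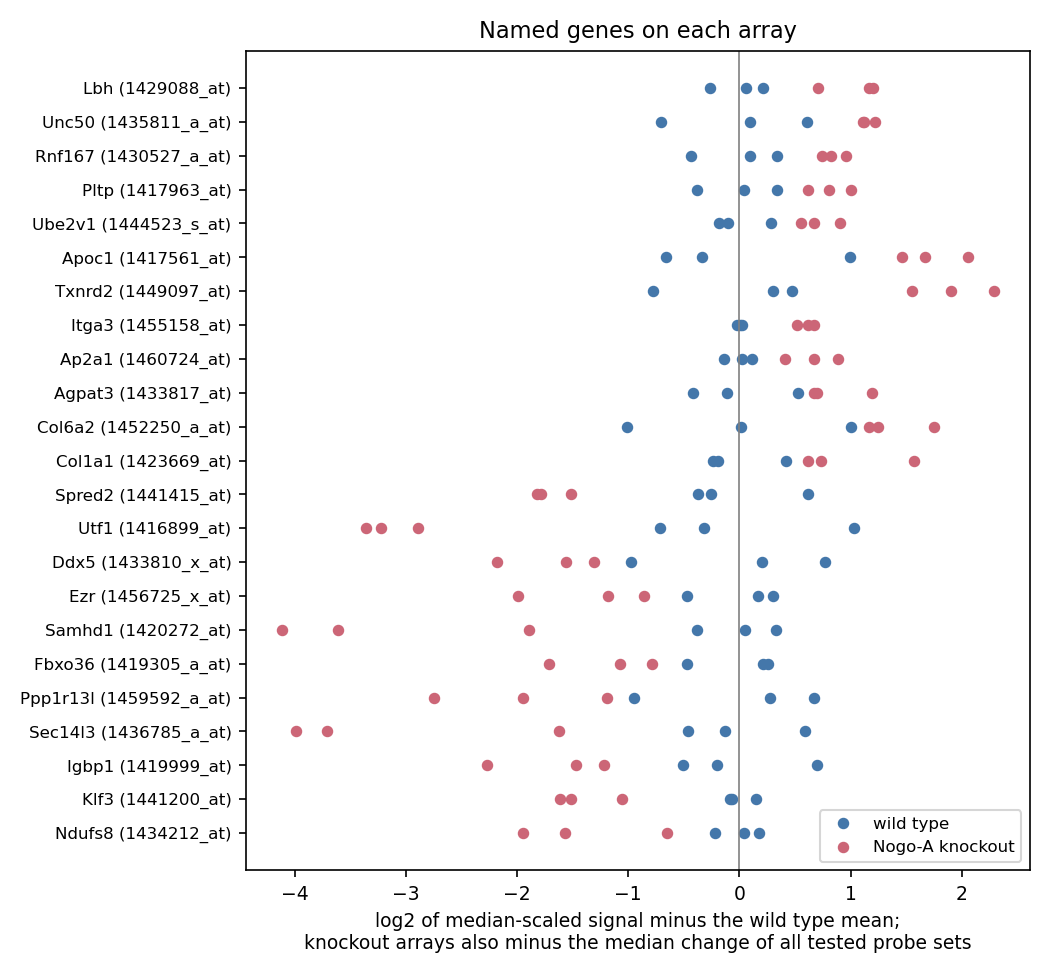
Log2 of the median-scaled signal of 23 named genes on each array, minus the wild type mean, with the median change of all tested probe sets also taken from the knockout arrays; each point is 1 array. By the rule that named the genes, the 3 knockout points lie to 1 side of the 3 wild type points in every row, and no gene shown here passed the adjusted threshold.

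The list of myelin and oligodendrocyte genes passed in camera on the higher side. The median of the 27 tested members was 0.21 above the shift on the log2 scale, a fold of 1.16 (camera, Benjamini-Hochberg adjusted p = 0.000624, but adjusted p = 0.952 with an estimated correlation), and 24 of 27 lay above it. The call was also lost after quantile normalization, where the median was 0.082 and camera's adjusted p was 0.0851, against a range of 1.74e-06 to 0.0851 over all alternatives. No member passed over all tested probe sets, and 3 passed adjusted over the list alone. These were Myrf, the transcription factor that switches on myelin genes, with 1544 ± 354 in wild type and 2372 ± 246 in knockout, Opalin, a membrane protein of oligodendrocytes, with 1592 ± 171 and 2235 ± 179, and Sox10, a factor of the oligodendrocyte lineage, with 1379.7 ± 333 and 1859 ± 343 (SD, n = 3 each). Their relative folds were 1.55, 1.399 and 1.35. Gjb1, a connexin, followed at 1.24-fold, Mbp and Cnp, which encode myelin proteins, had 1.23-fold and 1.22-fold, while Mog and Cldn11 had 0.968-fold and 0.949-fold. On the arrays the list stood at 0.044, -0.0027 and -0.046 in wild type and at 0.14, 0.12 and 0.22 in knockout. Such a separation of the genotypes, with knockout above, was seen in 9 of the 30 tested lists. The myelin list did not pass in fry (adjusted p = 0.154) or in fry's mixed test (adjusted p = 0.112). Schwann cell genes of nerve roots had a median of 0.18 over 10 members (camera adjusted p = 0.326), with Pmp22 at 1.36-fold and Ncmap at 1.27-fold past the threshold adjusted over the list alone, and oligodendrocyte precursor genes had 0.12 over 10 members (adjusted p = 0.779), led by Matn4 at 1.39-fold.

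Oxidative phosphorylation was the other list that passed. Its 37 tested members, subunits of the respiratory chain and of ATP synthase, had a median of 0.11 above the shift (camera adjusted p = 0.0478, and adjusted p = 0.952 with an estimated correlation), and 34 lay above it. Against random lists of genes of the same level the median was 0.011 higher, at percentile 80.1 of 10000 lists, within their 95% range. Ndufv1 and Ndufs1 of complex I were 1.17-fold each, and Cox5b of complex IV was 1.24-fold, with none past the threshold adjusted over the list alone. The call was lost after quantile normalization, where the median was 0.0033, and without wild type replicate 2 or any knockout replicate. Without these 4 arrays in turn the camera adjusted p was 0.122, 0.153, 0.124 and 0.0722. Across all lists, 2 passed, and 12, 1, 6 and 6 passed without wild type replicates 1, 2 and 3 and knockout replicate 3.

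Neuronal lists did not pass in camera. Microtubule and axonal transport genes had a median of 0.13 over 32 members (adjusted p = 0.0508), with the tubulin Tubb4a at 1.26-fold, the axonal protein Mapt at 1.23-fold and Klc1 of the kinesin motor at 1.20-fold. This list passed on the higher side with the deposited scaling (camera adjusted p = 0.000823), with centring on the tested probe sets (0.00208), without a filter (0.00121), with the 25th percentile filter (0.00286), without wild type replicate 1 (0.000965), without wild type replicate 3 (0.0290) and with the deposited scaling without that array (0.0188). All these calls used the preset correlation, and in the main fit with an estimated correlation the list's camera adjusted p was 0.952. The list did not pass after quantile normalization (0.651, median 0.0036), with the replicate block (0.227), without wild type replicate 2 (0.230) or without knockout replicate 1, 2 or 3 (0.118, 0.124 and 0.143). It also missed with the 75th percentile filter (0.314), the offset (0.0551), no trend (0.0518) and the mean of all probe sets (0.0959). Against random lists of the same level its median was 0.034 higher, within their 95% range. Motor neuron genes had 0.097 over 14 members (adjusted p = 0.102). Of these Ache, which breaks down acetylcholine, read 1051 ± 186 in wild type and 1456 ± 291 in knockout and passed adjusted over the list alone. Ion channels of nodes and axons had 0.078 over 17 members (adjusted p = 0.169), and the pacemaker channel Hcn2, at 838 ± 110 and 1207 ± 187, also passed adjusted over the list alone. Interneuron genes had 0.093 over 19 members (adjusted p = 0.354), led by the neuropeptide genes Sst at 1.31-fold and Tac2 at 1.29-fold, and synaptic vesicle genes had 0.082 over 24 members (adjusted p = 0.171), led by Syn1 at 1.18-fold. Immediate early genes, which follow neuronal activity, had -0.0063 over 14 members (adjusted p = 0.973), with Junb at 2.16-fold and Arc at 1.51-fold and neither past the threshold adjusted over the list alone. Dorsal root ganglion genes had 2 tested members and were not tested as a list, and Pou4f1 there was 1.17-fold.

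Lists tied to Nogo-A and to growth cones did not pass in camera. Nogo-A and its receptor pathway had a median of 0.056 over 17 members (adjusted p = 0.373), which count Rtn4 itself at its brightest probe set, 1.31-fold, and not at the lost one, with the co-receptor Lingo1 at 1.29-fold, the receptor S1pr2 at 1.53-fold and the actin-severing Cfl1 at 1.25-fold. The other reticulons and endoplasmic reticulum shaping genes had 0.16 over 12 members (adjusted p = 0.171), at percentile 98.75 of random lists of the same level. The Nogo-A pathway list stood at percentile 41.4. Such percentiles, here and below, are not adjusted over the lists and take genes as independent, while the estimated correlation of the reticulon list was 0.509. After quantile normalization the reticulon median was 0.038 (camera adjusted p = 0.538). Ckap4, a sheet-forming protein of the endoplasmic reticulum, passed adjusted over the list alone at 722 ± 42.6 in wild type and 988 ± 40.4 in knockout. Rtn1, a reticulon, was 1.15-fold. Guidance genes followed in 3 lists. Semaphorins and plexins had -0.083 over 31 members (adjusted p = 0.171), ephrins and Eph receptors 0.10 over 14 (adjusted p = 0.534), and netrin, Slit and other guidance genes -0.012 over 21 (adjusted p = 0.779), in which Ntn1, at 391 ± 24.4 and 561 ± 57.2, passed adjusted over the list alone. Genes of axon growth and regeneration had 0.022 over 27 members (adjusted p = 0.511), led by the heat shock gene Hspb1 at 1.29-fold.

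Connective tissue and blood genes were tested as markers of other cells in the sample. Collagen genes passed adjusted over the list alone among those of smooth muscle, pericytes and meninges, namely Col1a1 (254 ± 40.02 in wild type and 521 ± 213 in knockout), Col1a2 (1598 ± 319 and 2437 ± 263) and Col3a1 (963 ± 82.4 and 1327 ± 233). That list had a median of 0.095 over 20 members (camera adjusted p = 0.171). Col1a1 and Col1a2 were brightest, at 767 and 2704, on knockout replicate 2, the array with the most signal from skeletal muscle genes. Col3a1 was brightest on knockout replicate 1, at 1593. On wild type replicate 3, also bright in muscle genes, Col1a1 read 254, under the 293 of wild type replicate 1. Col3a1 read 954 there, also under the 1049 of replicate 1, but Col1a2 read 1869, above the 1678 and 1247 of wild type replicates 1 and 2. The list as a whole was highest in wild type on replicate 3, at 0.090. Skeletal muscle genes themselves had a median of 0.41 over 12 members (camera adjusted p = 0.503), none past adjusted over the list alone. Single arrays set its direction, since it passed as lower without knockout replicate 2 (camera adjusted p = 0.000372) and as higher without knockout replicate 1 (1.46e-09), knockout replicate 3 (1.10e-05) or wild type replicate 3 (0.000152), and with the replicate block (4.44e-05). These p-values used the preset correlation, while the correlation estimated in the main fit was 0.649 for this list. Among red blood cell genes, with 0.14 over 4 members (camera adjusted p = 0.0810), Slc4a1, the anion exchanger of the red cell membrane, passed adjusted over the list alone at 69.8 ± 11.97 and 228 ± 35.1. Tested with fry, which asks whether a list moves 1 way and does not compare it with other genes, the red blood cell list (adjusted p = 0.00329) and the smooth muscle, pericyte and meninges list (adjusted p = 0.0316) passed on the unshifted values, and the red blood cell list passed in fry's mixed test (adjusted p = 0.0116). The 4 red blood cell members had a mean of 0.52 against their median of 0.14. Slc4a1 lay under the array median on every wild type array, and the list was not tested without it. Endothelial genes had -0.13 over 16 members (camera adjusted p = 0.171), at percentile 0.12 of random lists of the same level, and Pecam1 had a fold of 0.647.

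Glial, immune and housekeeping lists did not pass in camera. Astrocyte genes had a median of 0.051 over 18 members (adjusted p = 0.534), and Gfap, the filament of reactive astrocytes, was 1.47-fold with wild type signals of 3726 to 9057.5. Microglia and macrophage genes had -0.013 over 17 members (adjusted p = 0.534), and Tyrobp was 1.08-fold. Reactive glia and complement genes had 0.00016 over 16 members (adjusted p = 0.818), with the calcium-binding S100a6 (1133 ± 198 and 1619 ± 154) and the hyaluronan receptor Cd44 (465 ± 66.5 and 608 ± 37.5) past the threshold adjusted over the list alone. Interferon response genes had 0.097 over 16 members (adjusted p = 0.828), led by Xaf1 at 1.17-fold. Ependymal and cilia genes had -0.20 over 9 (adjusted p = 0.0810), and Dnali1 had a fold of 0.588. Ribosomal protein genes had 0.082 over 25 (adjusted p = 0.171), cholesterol synthesis genes 0.070 over 19 (adjusted p = 0.171), with Mvk at 1.49-fold, and genes of heat shock and the unfolded protein response -0.028 over 23 (adjusted p = 0.677), at percentile 0.19 of random lists of the same level, with Calr at 1.19-fold. Genes of the glucocorticoid response and the circadian clock had 0.024 over 23 (adjusted p = 0.973), and the metallothionein Mt2 in that list read 7823 ± 1565 in wild type and 5004 ± 346 in knockout.

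Over the 30 lists with 586 members, 15 members passed adjusted over the list alone, all of them higher, and 0 members passed over all tested probe sets in limma. These p-values come from the unshifted fit, in which 91.4% of all unadjusted calls were higher, against 51.9% with the deposited scaling. The shared direction is therefore not a result about these members, and their adjustment over the list alone was not repeated under another scaling. No list passed with an estimated correlation, where the smallest adjusted p was 0.952. Without wild type replicate 1 camera also called the motor neuron (adjusted p = 0.0445), synaptic vesicle (0.0306), ion channel (0.0306) and cholesterol (0.0194) lists higher and the semaphorin (0.0425), microglia (0.0306), endothelial (0.0306) and ependymal (0.0306) lists lower. Without wild type replicate 3 it called the smooth muscle and red blood cell lists higher (0.0338 each), and without knockout replicate 3 the motor neuron and smooth muscle lists higher (0.0488 each) and the endothelial (0.0488) and ependymal (0.0181) lists lower. Without a filter it also called higher the reticulon (0.0214), axon growth (0.0491), motor neuron (0.0400), interneuron (0.0322), synaptic vesicle (0.00707), ion channel (0.00899), smooth muscle (0.0400) and cholesterol (0.00669) lists, and with the 25th percentile filter the synaptic vesicle, ion channel and cholesterol lists (0.0290 each) and the red blood cell list (0.0286). The red blood cell list was also higher without the trend (0.0245), the ribosomal list higher with the deposited scaling (0.0206), and the endothelial list lower with the 75th percentile filter (0.0119). After quantile normalization the heat shock and unfolded protein response list was the 1 list called, as lower (0.0253). Quantile normalization turned the sign of 5 medians, those of the ribosomal, Nogo-A pathway, astrocyte, reactive glia and immediate early lists. In 5 lists the median, the mean and camera's direction did not share a sign, namely the netrin, reactive glia, interferon, glucocorticoid and immediate early lists.

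**Figure D3:**
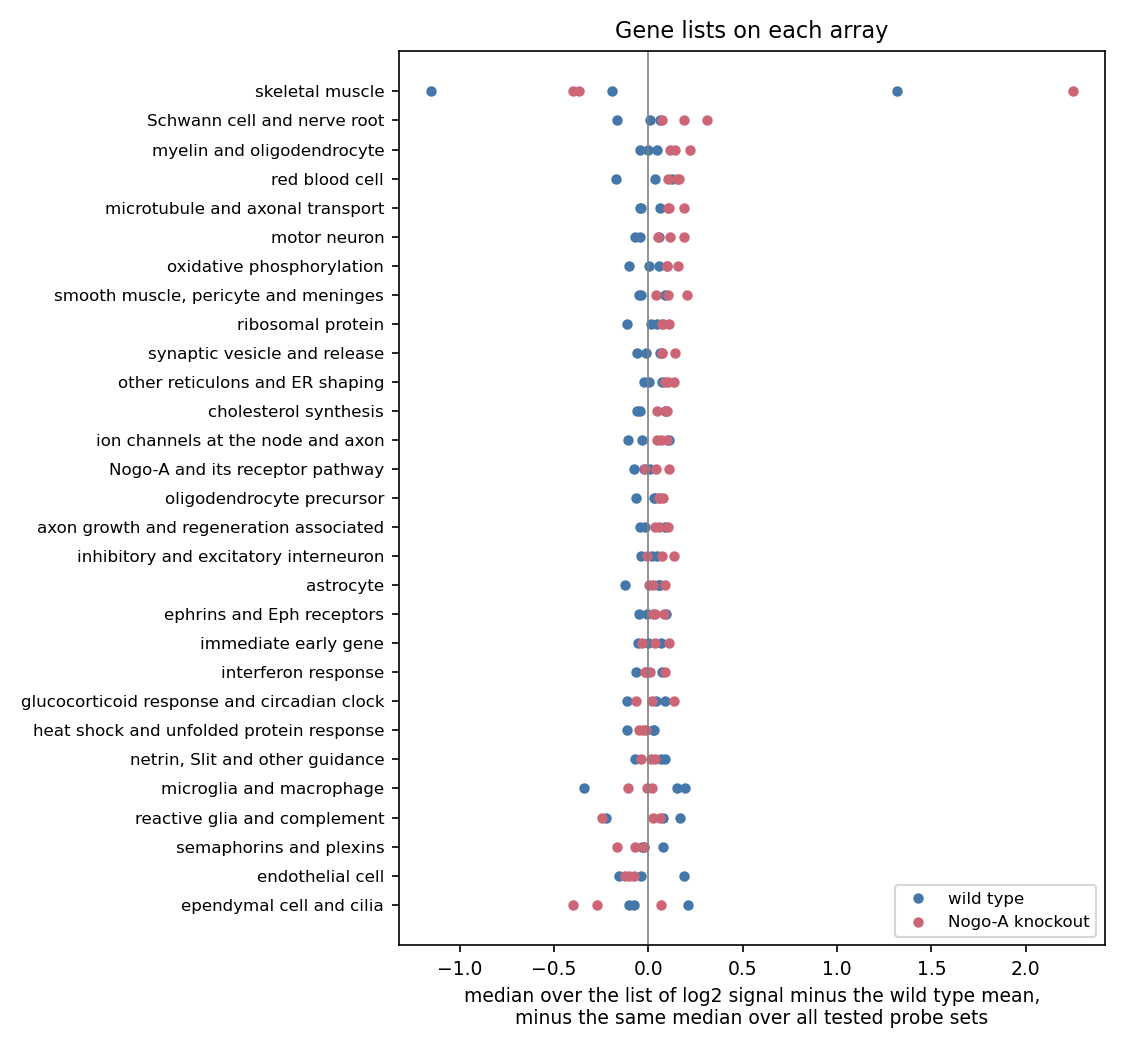
Median over each tested list reported here of log2 signal minus the wild type mean, less the same median over all tested probe sets, with 1 point per array (3 wild type, 3 Nogo-A knockout). The myelin and oligodendrocyte list stands at 0.12 to 0.22 on the knockout arrays and at -0.046 to 0.044 on the wild type arrays, and the skeletal muscle list at 1.32 on wild type replicate 3 and 2.25 on knockout replicate 2.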

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

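Centring on the tested probe sets, and the deposited scaling without wild type replicate 3, were chosen after the data were seen, and all other alternatives were planned. Log2 changes of genes and probe sets in this part are not taken relative to the shift of 0.23, and medians of lists are. The loss at the third brightest Rtn4 probe set in wild type kept its direction under every alternative, with a log2 change of -6.61 to -8.58 when 1 array was left out and of -5.45 with the offset, and lost its call only without the trend in eBayes, at -7.40 with an adjusted p of 0.0610 in limma. Of 380 values of named genes under alternatives, 326 kept their direction and side of the threshold, 53 moved past it and 1 reversed, Ndufs8, at 0.032 with the mean of all its probe sets, a value under that shift.

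The count of probe sets higher, 0 as reported, was 14 with the 75th percentile filter, 1 with the offset, 2 without the trend, 1 with the deposited scaling without wild type replicate 3, and 0 to 640 with 1 array left out. The count lower, 1 as reported, was 3, 1, 0, 2 and 1 to 38 in that order. Both were highest without wild type replicate 1, which left the pair of wild type arrays with raised dim signals. The methods' t-test called 992 probe sets after quantile normalization, 1136 with the deposited scaling, 3499 without a filter, 1387 with the 75th percentile filter, 1222 with centring on the tested probe sets, 1226 with the deposited scaling without wild type replicate 3, and 931 to 5423 with 1 array left out, against 2181 as reported. The cause of these shifts was not tested apart from the scaling, which by construction sets the share of higher calls.

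Lists past the threshold, 2 as reported, numbered 1 after quantile normalization, 5 with the deposited scaling, 12 without a filter, 8 with the 25th percentile filter, 1 with the offset, 1 with the mean of all probe sets of a gene, and 1 to 12 with 1 array left out. The myelin and oligodendrocyte list lost its call only after quantile normalization, at a median of 0.082, and stood at 0.13 to 0.21 with 1 array left out. The oxidative phosphorylation list lost its call after quantile normalization at 0.0033, with the 75th percentile filter at 0.077, with the offset at 0.13, with the mean of all probe sets at 0.075 and with the deposited scaling without wild type replicate 3 at 0.070, and ranged from 0.070 to 0.16 with 1 array left out. The cause was not tested. With 1 array left out, the other Rtn4 probe sets, from the brightest to the dimmest, had log2 changes of 0.38 to 0.76, 0.63 to 0.96, 0.43 to 0.84 and 0.68 to 1.11, each lowest without wild type replicate 3, and the second brightest and the dimmest passed without wild type replicate 1. Quantile normalization left 0.26, 0.44, 0.41 and 0.69, against 0.62, 0.78, 0.68 and 0.92 as fitted. The odds ratio for genes near Rtn4, 0.514 as reported, turned above 1 after quantile normalization (1.57), with the deposited scaling (1.43), with centring on the tested probe sets (1.38) and with the deposited scaling without wild type replicate 3 (1.19), and ranged from 0.433 to 1.34 with 1 array left out.

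With the label's number as a replicate block, limma called 182 probe sets higher and 33 lower, the methods' t-test called 1375, the dimmest Rtn4 probe set passed at 0.92, and the oxidative phosphorylation list lost its call at 0.11. Whether the numbers pair the animals stays open. The deviations of same-numbered arrays correlated at -0.035, 0.074 and 0.11 for replicates 1 to 3, which was the best match of wild type replicates 2 and 3, while wild type replicate 1 correlated best with knockout replicate 2, at 0.080.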

Other observations

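Tests of the excess of higher probe sets, of the myelin list and of the other Rtn4 probe sets were chosen after those results were seen, and the test of genes near Rtn4 and the splits of the arrays were planned. Within 10 Mb of Rtn4 in the GRCm38.p6 table, 5 of 62 tested genes (8.06%) had an unadjusted p under 0.05 in limma, against 1684 of 11544 (14.6%) elsewhere. These were Nprl3, a regulator of nutrient signalling, at 1.32-fold relative to the shift, Commd1, which acts in copper balance, at 1.34-fold, the neuronal vesicle protein Nsg2 at 1.16-fold, the potassium channel partner Kcnip1 at 1.18-fold and Bod1, which acts in chromosome alignment, at 1.12-fold. None passed the adjusted threshold, with an adjusted p of 0.382 each in limma. Spred2, which had the smallest p on the lower side after Rtn4 at a dimmer probe set, also lies within 10 Mb. A piece of another strain's chromosome kept around the targeted gene is a possible explanation for changes there, but the odds ratio of 0.514 had an interval of 0.160 to 1.27 (Fisher's exact test, two-sided p = 0.203) and turned above 1 under the other scalings, so this cannot be told apart from no such effect.

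Among probe sets without a gene name here, 1 came nearest to the threshold after Rtn4 and was named after its values were seen. It read 138 ± 63.5 in wild type and 753 ± 490.0 in knockout (SD, n = 3 each), 5.15-fold relative to the shift, with an adjusted p of 0.0501 in limma. Another unnamed probe set read 296.0 ± 140.1 and 824 ± 400.0, and on both the brightest array was knockout replicate 3. A further one read 369 ± 81.9 and 670 ± 137. An unnamed probe set that was lower in knockout read 815 ± 322 and 270 ± 78.8, and it passed without wild type replicate 2. The probe set nearest to the threshold passed with the offset and without wild type replicate 2, wild type replicate 3 or knockout replicate 1. Of other muscle genes, Ckm and Tnnt3 were brightest on the same arrays as Acta1 and Myh4, while Pygm ranged only from 927 to 1382 over the 6 arrays and was brighter on knockout replicate 1 than on 2. Ckm, the creatine kinase of muscle, read 725 on wild type replicate 3 and 1269 on knockout replicate 2 against 115 to 259 on the other 4, and Tnnt3, a troponin, read 795 and 1345 against 133 to 273.

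More probe sets were higher than lower in knockout, 2805 against 265 at an unadjusted p under 0.05. Raised dim signals on wild type replicates 2 and 3, which lift the medians those arrays were divided by, are a candidate explanation, and a rise of expressed genes throughout the knockout cord is another. They cannot be told apart here. With the deposited scaling 51.9% of the unadjusted calls were higher in place of 91.4%, but the scaling itself sets this share, so it supports neither. The median log2 change against wild type replicate 1 alone was 0.019, against 0.21 for replicate 2 and 0.45 for replicate 3. The methods' t-test gave 2181 probe sets, and of the 10 splits of the 6 arrays into 3 and 3, the real one included, 1 gave as many, the real one, with 1406 as the highest of the others. With the deposited scaling it gave 1136, and the split with wild type replicates 1 and 2 and knockout replicate 2 on one side gave 1556. In limma, the count of 1 was met by 2 splits, the real one included, with 2 as the highest other. With 10 splits no share under 0.05 can be had.

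The myelin and oligodendrocyte list was higher in knockout by a median of 0.21 on the log2 scale. Compression of bright signals on wild type replicates 2 and 3 as the whole cause is argued against by lists of random genes of the same level, since the list's median stood at percentile 100 of 10000 such lists, 0.11 above their median, although quantile normalization left only 0.082 and ended the call. The random lists take genes as independent, and the skeletal muscle list, set by single arrays, also stood at percentile 100, while oxidative phosphorylation, the other list called, stood at percentile 80.1. More nerve root tissue on the knockout arrays as the whole cause was examined with 7 genes of central myelin and oligodendrocytes, whose median was 0.20982. They were members of the myelin list chosen after its call, and the criterion was changed after its result was seen. Being drawn from a list already called higher, these genes cannot decide the question. Against genes of the same level they stood 0.14756 higher, just past 2 standard errors over the genes (0.14721), and 0.067 higher as a median per array (95% interval 0.013 to 0.12 over the 3 and 3 arrays). Nerve root tissue as all or part of the cause stays open, and the Schwann cell list had a median of 0.18 and stood at percentile 98.6 of random lists of its level. A change in oligodendrocytes of animals without Nogo-A and a larger share of white matter in the tissue taken also stay open, and neither was tested. Of 10 splits, 7 gave at least the 2 lists called, the real one included, with 5 as the highest other, 10 splits are too few for a share under 0.05, and 0 of the other splits called the myelin list.

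The 4 other Rtn4 probe sets were brighter in knockout by 1.31-fold to 1.61-fold relative to the shift. Compression of bright signals as the whole cause is argued against by the 500 probe sets nearest in level, of which at least 98.6% had a lower log2 change than the Rtn4 probe set, at each of the 4. Wild type replicate 3 alone as the cause is argued against by the deposited scaling without that array, under which the smallest of the 4 log2 changes was 0.26 and the median of all tested probe sets -0.0042. None passed over all probe sets, with an adjusted p of 0.382 each in limma. Which transcripts each probe set detects is not known here, so higher levels of the remaining Rtn4 transcripts and a change of the targeted transcript that keeps its other parts both stay open and untested.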
